A study of Mus musculus with 12 samples.

How the data were processed

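The series holds 12 samples of mouse T cells of the strain C57BL/6, of which 6 are RNA-seq libraries and 6 are chromatin immunoprecipitation or input samples, which are not analysed here. Per the labels' protocols, CD4+ T cells were purified from spleen and activated with anti-CD3 and anti-CD28 plus IL-6 at 20 ng/mL and TGF-beta at 2.5 ng/mL, conditions that direct naive cells to the Th17 fate. They were kept in culture for 48 to 72 h and then exposed to compound for 2 h, and libraries were made from polyA-selected RNA. Groups were taken from the sample titles: JQ1, MS402, and a control group whose titles name no compound, with 2 libraries each. Whether the control cells received vehicle, and the concentrations of both compounds, are not given in the sources used here. Nothing in the labels says whether the 2 libraries of a group came from separate animals or cultures.

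The deposited table gives 1 value for each of 17778 gene symbols in each of the 6 libraries, and the values the authors deposited are on a log2 scale, not counts. CASAVA 1.4, Bowtie2, TopHat2 2.1.0, HTSeq, DESeq2 and the genome build mm9 are named in the submitters' processing notes, without the role of each. The annotation and the strand setting of the counting are not given in the sources used here, so reads of overlapping or antisense genes and of near-identical gene copies cannot be told apart. The values follow the closed form of a variance-stabilizing transformation: solving it with the lowest value of the table, 4.67, as its constant gave normalized counts that were whole multiples of a step per library. Within a tolerance of 1e-06, 100% of the recovered values were whole reads, and the largest deviation was 1.41e-08. The steps equalled the median-ratio size factors recomputed from the recovered reads. Normalized counts in the text are these reads divided by the size factor, and log2 differences are on the deposited scale, which understates the fold change of genes with few reads. Gene symbols were matched to a table of mouse gene names of the assembly GRCm38.p6, used for names only: 17021 were current symbols, 696 were older names and 61 were in neither. Coordinates are not printed because that assembly is not the build in the submitters' processing notes.

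Genes with at least 10 normalized counts in at least 2 libraries were tested (13447 genes). A linear model with 1 mean per group was fitted to the log2 values of all 6 libraries in limma 3.58.1 under R 4.3.3, so that the groups share 1 estimate of the spread per gene, moderated with a trend on expression level. P-values were adjusted by the Benjamini-Hochberg method, and genes with a limma adjusted p under 0.05 were called. A quasi-likelihood test of raw counts had been planned before the data were examined. The deposited values turned out to be on a log2 scale, so limma was used on them in its place, and a further test of raw counts, also intended, was not run. The recovered reads were tested with voom, as given below. Gene lists, 23 in number and fixed before the data were examined, were tested with camera at a preset correlation of 0.01 between genes, with camera at an estimated correlation, and with fry, each adjusted over the lists. The lists covered Th17 cytokines and effectors, Th17 transcription factors, Th1 genes, Th2 genes, Treg genes, immediate early genes, Myc and ribosome biogenesis, BET and P-TEFb components, histone genes, cell cycle genes, cytokine receptor and JAK-STAT genes, NF-kB target genes, naive and quiescence genes, glycolysis genes, cholesterol synthesis genes, stress response genes, interferon response genes, apoptosis regulators, T cell identity genes, and markers of B cells, myeloid cells, CD8 and NK cells, and erythroid cells.

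Named genes were also chosen by a rule fixed before the data were examined. It took 12 genes in every comparison (Il17a, Il17f, Il21, Rorc, Myc, Hexim1, Brd2, Brd4, Foxp3, Tbx21, Gata3 and Batf), the 8 called genes with the largest rise and the 8 with the largest fall, and up to 4 genes of each list with the smallest p. Candidates for the largest changes had a mean log2 CPM of at least 4 and no overlap between the libraries of the groups compared, and predicted or unnamed genes and small RNA host symbols (Mir, Snor and Sno) were left out. In the comparison of the compounds, the genes with the largest change in the other comparisons were named too, each with the 95% interval of the difference. Since JQ1 and MS402 were compared with the same controls, 50 sets of unchanged groups were simulated against those controls, and the values they gave are printed beside the observed ones.

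Library depth was 32624032 to 48350693 reads assigned to genes. The method was tested on simulated data with 13259 genes. They were drawn independently from the control means and the spread of replicate pairs, and 200 were changed in the JQ1 libraries. Limma called 10419 genes for JQ1 in the data, far more than were changed here, so the rates below do not carry over to it. With 50 changed genes per size, it recovered 22% of changes of 1.1-fold, 62% of 1.25-fold, 78% of 1.5-fold and 92% of 2-fold, and called 5 unchanged genes. Among changed genes with a control mean of at least 100, recovery was 28.2%, 79.5%, 100% and 100%. A first simulation stopped at its own bound for 2-fold changes, and the bound was then applied to genes with a control mean of at least 100, so this limit was revised after a result. In a simulation of MS402 against control, a list of 30 genes shifted by 0.4 (log2) was called by camera with both correlations, and 0 of 20 random lists were called. All other genes were unchanged and drawn independently there, so it does not test camera where most genes move together. Alternatives were other scalings (upper-quartile and total counts), other filters on low counts, stricter thresholds, the replicate number as a block, fits of only the 4 libraries compared, and fits that left out each library in turn. Further analyses were chosen after seeing the data: voom on the recovered reads, log2(normalized count + 1), a fit without the variance trend, and TMM, which had been planned as the main scaling. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.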

Results

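Gene expression was measured by RNA-seq in mouse Th17 cells, the IL-17-producing helper T cells, after 2 h with JQ1, after 2 h with MS402, or with no compound named (control), with 2 libraries per group. JQ1 blocks both bromodomains of the BET proteins (BRD2, BRD3, BRD4 and BRDT), which bind acetylated chromatin and help RNA polymerase II to elongate. The series title presents MS402 as acting on the N-terminal BET bromodomain, and the series asks how blocking that domain bears on Th17 differentiation. Reads assigned to genes numbered 40346419 and 38553183 for control, 45129365 and 38526807 for JQ1, and 32624032 and 48350693 for MS402. Each mean below is in normalized read counts with its SD over 2 libraries, and each log2 difference has its standard error after the ± sign. On the deposited scale, log2 differences of genes with few reads are smaller than those of their counts. All scalings are relative to the other genes of a library, so a change of total RNA would not show in these values.

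The libraries fell into 3 pairs by group. Across the 13447 tested genes, Pearson's r of the log2 values was 0.9987 to 0.9989 within groups, 0.9945 to 0.9949 between JQ1 and MS402, 0.9793 to 0.9797 between control and MS402, and 0.9665 to 0.9668 between control and JQ1 (genes are not independent replicates). The first principal component held 88.4% of the variance and the next 7.15%. Libraries of one group differed by more than counting noise, for which a chi-square per gene near 1 is the reference. It was 1.57 for control, 1.89 for JQ1 and 3.35 for MS402. For genes above 1000 counts the variation beyond counting was still small, at 1.38%, 1.45% and 2.69%. Because separate cultures or animals are not stated, all p-values measure only the spread between these libraries, which may be technical.

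What JQ1 changed in Th17 cells was asked first. The transcript of Myc, the growth-promoting transcription factor, was 7.29-fold lower, at 13417 ± 204 in control and 1840 ± 69.2 with JQ1 (SD, n = 2). Rorc, which encodes the Th17 master regulator RORγt, was 3.50-fold lower (3207 ± 105 and 917 ± 17.7). Batf, an AP-1 factor needed for Th17 differentiation, was 3.77-fold lower (3017 ± 57.5 and 801 ± 57.6). The cytokine transcripts moved less: Il21 was 1.80-fold lower, Il17a 1.23-fold lower and Il17f 1.05-fold lower. Hexim1, the inhibitor of the elongation factor P-TEFb, was 5.19-fold higher (1268 ± 51.1 and 6576 ± 49.2).

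On the log2 scale Myc fell by 2.83 ± 0.033 (limma adjusted p = 2.40e-82), Rorc by 1.75 ± 0.048 and Batf by 1.85 ± 0.049, while Hexim1 rose by 2.33 ± 0.036 (limma adjusted p = 6.45e-73). The difference was -0.85 ± 0.024 for Il21, -0.29 ± 0.035 for Il17a (limma adjusted p = 1.34e-12) and -0.076 ± 0.026 for Il17f (limma adjusted p = 0.00592). Among regulators of other helper fates, Tbx21 of Th1 cells (-0.64 ± 0.055) and Foxp3 of regulatory T cells (-0.45 ± 0.065) fell, and Gata3 of Th2 cells rose (0.23 ± 0.045, limma adjusted p = 4.97e-06). The BET genes themselves rose, Brd2 by 0.87 ± 0.025 and Brd4 by 0.20 ± 0.028. The call of Il17f was lost without control replicate 1 (limma adjusted p = 0.0902), without JQ1 replicate 2 (0.0662) and without the variance trend (0.0805).

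**Figure D1:**
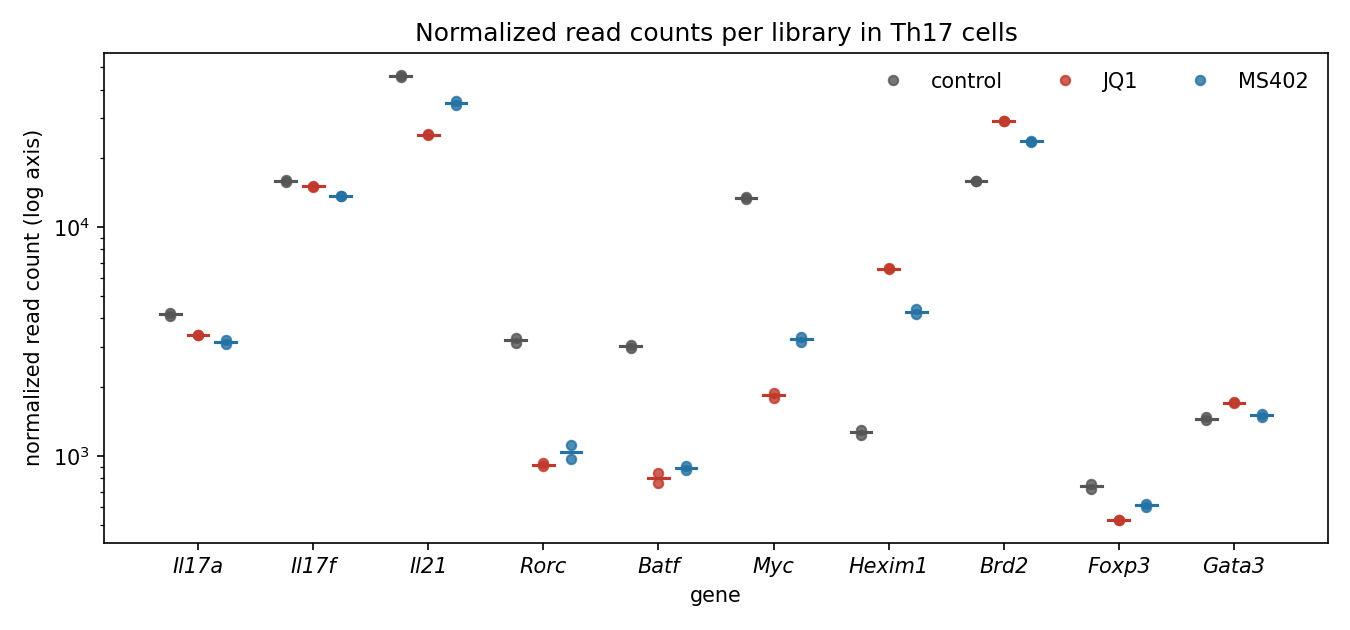
Normalized read counts (vertical axis, log scale) of 10 genes named before the data were examined, 1 point per library and a bar at each group's mean (control grey, JQ1 red, MS402 blue). Rorc, Batf and Myc lie far below control with both compounds, Hexim1 lies above it, and Il17a and Il17f differ little between groups.

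The largest rises with JQ1 were taken among genes with a mean log2 CPM of at least 4, which leaves out Hspa1a, Hspa1b, Hist1h1c and Hist1h2bc. They were in Bzrap1, which encodes a RIM-binding scaffold protein (482 ± 30.3 to 7991 ± 60.0, 16.6-fold), the ETS factor Etv5 (2.60 ± 0.056), the Wnt receptor Fzd5 (2.59 ± 0.060), Sipa1l2 (2.47 ± 0.042) and the potassium channel Kcnc3 (2.43 ± 0.062). Hexim1, the antiproliferative gene Tob1 (2.33 ± 0.047) and Pdlim7 (2.33 ± 0.054) completed the 8. Fut7, whose fucosyltransferase builds selectin ligands, had the largest fall (2335 ± 19.4 to 246 ± 27.3, 9.50-fold) under the same limit, which leaves out Ccr5. Next came Myc, the connexin gene Gja5 (-2.80 ± 0.051), Gcnt2 (-2.64 ± 0.047) and Ubash3a, a negative regulator of T cell receptor signalling (-2.50 ± 0.064). Slfn1 (-2.44 ± 0.054), the chemokine receptor gene Ccr4 (-2.43 ± 0.034) and the Polycomb-associated gene Phf19 (-2.37 ± 0.063) followed. Among these 16 genes the highest limma adjusted p was 7.59e-54. Slfn1 belongs to a family of similar genes whose reads the counting could have split.

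Of 19 tested Th17 cytokines and effectors, 16 fell and 2 rose with JQ1 (median -0.85; camera adjusted p = 4.27e-05; adjusted p = 0.145 with an estimated correlation). Il6ra, the IL-6 receptor chain, fell from 4820 ± 60.9 to 1894 ± 48.6, Il10 from 18713 ± 241 to 8932 ± 116 and Il24 from 13749 ± 13.7 to 7155 ± 117. Th17 transcription factors went both ways (11 lower and 7 higher of 18, camera adjusted p = 0.103). Ahr (-1.11 ± 0.029) and Etv6 (-1.09 ± 0.030) fell with Batf and Rorc, and Junb rose (0.99 ± 0.026). That list was called without control replicate 1 (camera adjusted p = 0.0162) and without control replicate 2 (0.0254).

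Genes of the other helper fates were mostly lower as well. Among Th1 genes, 14 of 16 fell and 1 rose (camera adjusted p = 0.00263; adjusted p = 0.230 with an estimated correlation), for example the IL-12 receptor gene Il12rb2 (-1.19 ± 0.028), Ccr5 (-2.92 ± 0.074) and Runx3 (-0.54 ± 0.028). Th2 genes showed 9 falls and 2 rises among 12 (camera adjusted p = 0.00271; adjusted p = 0.183 with an estimated correlation), with Ccr8 (-1.15 ± 0.036), Stat6 (-0.78 ± 0.030) and Gfi1 (-2.26 ± 0.11) beside Ccr4. In the Treg list 15 of 20 fell and 3 rose (camera adjusted p = 0.00271; adjusted p = 0.176 with an estimated correlation). Gpr83 (-1.83 ± 0.045), the ectonucleotidase gene Entpd1 (-1.15 ± 0.045) and Tnfrsf18 (-0.61 ± 0.027) were lower. Ctla4, an inhibitory receptor, went from 23501 ± 152 to 61155 ± 234. T cell identity genes fell in 11 of 15 cases and rose in 1 (camera adjusted p = 1.18e-04; adjusted p = 0.201 with an estimated correlation), for example Cd2 (-0.90 ± 0.027), Cd5 (-0.89 ± 0.028), Cd6 (-0.89 ± 0.028) and the kinase gene Lck (-0.84 ± 0.027).

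Markers of other cells were at low levels beside these. T cell identity genes summed to 5155 CPM in control and 3792 CPM with JQ1, and B cell markers to 98.9 and 64.4. Smaller sums were those of CD8 and NK cell markers (42.5 and 23.6), myeloid markers (4.79 and 3.90) and erythroid markers (2.23 and 2.38). All 7 tested CD8 and NK cell markers were lower with JQ1, such as Klrk1 (-1.57 ± 0.13) and Prf1 (-0.85 ± 0.14). As a list they missed the threshold (camera adjusted p = 0.0615), but passed without MS402 replicate 1 (0.0430), MS402 replicate 2 (0.0433) or the filter on low counts (0.0108). Of 10 B cell markers 7 were lower, with Cd22 at -1.41 ± 0.077 and Cd79b at -1.58 ± 0.089 (camera adjusted p = 0.147). Myeloid markers (1 higher, 1 lower of 8, camera adjusted p = 0.843) and erythroid markers (1 higher, 1 lower of 3, camera adjusted p = 0.926) were near their detection limit.

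Growth genes fell with JQ1. In the list of Myc and ribosome biogenesis, 25 of 30 genes fell and 4 rose (camera adjusted p = 5.70e-10; adjusted p = 0.145 with an estimated correlation). The nucleolar genes Gnl3 (-1.63 ± 0.040) and Mybbp1a (-1.01 ± 0.027) and Polr1b, a subunit of RNA polymerase I (-1.83 ± 0.046), were among the falls. Cell cycle genes fell in 19 of 24 cases and rose in 3 (camera adjusted p = 6.71e-04; adjusted p = 0.145 with an estimated correlation). The proliferation marker Mki67 (36081 ± 87.6 to 19304 ± 481), the mitotic kinase gene Plk1 (-0.91 ± 0.036) and the replication genes Mcm3 (-0.80 ± 0.027) and Mcm2 (-0.74 ± 0.029) fell with them.

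Histone genes, immediate early genes and most BET and P-TEFb components rose. Of 19 histone genes 16 rose and 0 fell (camera adjusted p = 8.19e-06; adjusted p = 0.145 with an estimated correlation). H3f3b stood at 19663 ± 45.3 and 64263 ± 789, H1f0 at 3828 ± 105 and 14055 ± 274, and Hist1h2bc at 62.4 ± 12.6 and 937 ± 10.7 (SD, n = 2). Replication-dependent histone genes are near-identical and mostly lack polyA tails, so their single values are uncertain. Immediate early genes rose in 21 of 26 cases and fell in 4 (camera adjusted p = 2.51e-06; adjusted p = 0.229 with an estimated correlation), for example Egr1 (2.12 ± 0.028), Nr4a1 (1.66 ± 0.028) and Nr4a3 (1.55 ± 0.031). BET and P-TEFb components showed 11 rises and 3 falls among 14 (camera adjusted p = 0.00377; adjusted p = 0.229 with an estimated correlation). Among them were Mepce (1.16 ± 0.033), which like Hexim1 belongs to the complex that holds P-TEFb inactive, and the elongation factor gene Ell2 (1.20 ± 0.046).

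Glycolysis genes rose in 15 of 18 cases and fell in 1 (camera adjusted p = 8.82e-04; adjusted p = 0.337 with an estimated correlation). The phosphofructokinase gene Pfkl (1.06 ± 0.026), the glucose transporter gene Slc2a1 (0.63 ± 0.025) and Aldoa (0.45 ± 0.024) rose and Pfkfb3 fell (-1.03 ± 0.036). Stress response genes, 12 higher and 7 lower of 20, just passed (camera adjusted p = 0.0447; adjusted p = 0.337 with an estimated correlation). Examples are the heat shock genes Hspa1b (42.0 ± 1.94 to 1322 ± 105) and Hspa1a (19.1 ± 9.46 to 988 ± 18.1), near-identical copies, and the endoplasmic reticulum chaperone gene Hspa5 (1.01 ± 0.024). That call was lost without MS402 replicate 1 (camera adjusted p = 0.0807), without MS402 replicate 2 (0.0808) and under total-count scaling (0.0629), among others.

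Other lists missed the threshold. Cytokine receptor and JAK-STAT genes split into 11 lower and 10 higher of 25 (camera adjusted p = 0.178, or 0.0420 without control replicate 1), with Bcl3 (-1.58 ± 0.037), Il12rb1 (-1.25 ± 0.030) and Il7r, the IL-7 receptor gene (-1.67 ± 0.040), lower. NF-kB target genes (14 lower, 6 higher of 25, camera adjusted p = 0.175) held Traf1 (-1.24 ± 0.038) and the inhibitor gene Nfkbia (0.79 ± 0.028). Naive and quiescence genes (11 lower, 7 higher of 18, camera adjusted p = 0.332) held Btg1 (1.13 ± 0.025), Txnip (1.11 ± 0.031) and Ccr7 (0.77 ± 0.024), all higher. Cholesterol synthesis genes (10 higher, 5 lower of 18, camera adjusted p = 0.202), interferon response genes (5 higher, 8 lower of 17, camera adjusted p = 0.612) and apoptosis regulators (3 higher, 10 lower of 18, camera adjusted p = 0.178) were not called. Their members include Idi1 (0.57 ± 0.030), Usp18 (-1.26 ± 0.070) and the pro-apoptotic gene Bcl2l11 (1.59 ± 0.036).

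In all, limma called 10419 of 13447 genes between JQ1 and control, 5186 higher and 5233 lower. Of these, 3858 differed by at least 1.5-fold on the deposited log2 scale (1829 higher, 2029 lower) and 1423 by at least 2-fold (672 higher, 751 lower). That scale undercounts such genes where reads are few. Camera called 12 of 23 lists (5 up, 7 down) and 0 with an estimated correlation (6 at an unadjusted p under 0.05), and fry, which tests a list without comparing it with other genes, called 20. Counts adjusted over the list alone equalled those over all genes for each list except the myeloid markers, of which 0 in place of 2 passed.

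What MS402 changed was asked next. Myc was 4.13-fold lower, at 3248 ± 116 against 13417 ± 204 in control (SD, n = 2). Rorc was 3.08-fold lower at 1041 ± 102, and Batf was 3.40-fold lower at 888 ± 23.2. Il17a was 1.32-fold lower, Il21 1.31-fold and Il17f 1.16-fold. Hexim1 was 3.37-fold higher at 4279 ± 148, and Bzrap1 was 8.22-fold higher at 3967 ± 181. T cell identity genes were lower in each of 15 tested cases.

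On the log2 scale the differences were -2.03 ± 0.033 for Myc (limma adjusted p = 7.81e-70), -1.58 ± 0.048 for Rorc, -1.71 ± 0.049 for Batf and 1.72 ± 0.036 for Hexim1. Il17a (-0.40 ± 0.035, limma adjusted p = 2.54e-18), Il17f (-0.22 ± 0.026, limma adjusted p = 3.37e-12) and Il21 (-0.39 ± 0.024) fell, as did Tbx21 (-0.44 ± 0.055) and Foxp3 (-0.25 ± 0.065). Brd2 (0.57 ± 0.025) and Brd4 (0.12 ± 0.028, limma adjusted p = 1.61e-04) rose, and Gata3 was not called (0.049 ± 0.045, limma adjusted p = 0.329). The call of Brd4 was lost without control replicate 1 (limma adjusted p = 0.0505).

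The largest rises with MS402 were taken under the same limit on expression, which leaves out Hspa1a, Hspa1b, Hist1h1c and Hist1h2bc. The 8 were Bzrap1 (2.92 ± 0.039), Etv5 (2.13 ± 0.056), Trim62 (2.05 ± 0.062), Sipa1l2 (2.00 ± 0.042), Pdlim7 (1.89 ± 0.054), Kcnc3 (1.83 ± 0.062), Neto2 (1.83 ± 0.048) and Fzd5 (1.82 ± 0.060). Gja5 fell furthest (4244 ± 23.9 to 738 ± 56.6, 5.75-fold) under that limit, which leaves out Ccr5. After Gja5 came Ubash3a (-2.06 ± 0.064), Myc and Fut7 (-1.94 ± 0.064). Cyp1a1, a target of the aryl hydrocarbon receptor, fell from 2506 ± 109.6 to 628 ± 3.77. The leukotriene receptor gene Cysltr1 (-1.91 ± 0.043), the PI3-kinase gene Pik3cg (-1.86 ± 0.039) and Ncf1 of the NADPH oxidase (-1.82 ± 0.042) made up the rest. The highest limma adjusted p of these 16 genes was 1.72e-45.

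Th17 cytokines and effectors fell in 16 of 19 cases and rose in 2 (camera adjusted p = 1.18e-05; adjusted p = 0.109 with an estimated correlation). Il6ra (-1.32 ± 0.038), the cytokine gene Lif (-0.88 ± 0.026), the leukotriene B4 receptor gene Ltb4r1 (-1.48 ± 0.058) and Il24 (-0.67 ± 0.028) are examples. Th17 transcription factors, 12 lower and 6 higher of 18, were called (camera adjusted p = 0.00319; adjusted p = 0.130 with an estimated correlation), among them Etv6 (-1.12 ± 0.030) and Ahr (from 11016 ± 223 to 5488 ± 61.8). Th1 genes fell in 13 of 16 cases and rose in 0 (camera adjusted p = 2.41e-04; adjusted p = 0.175 with an estimated correlation). Th2 genes fell in 11 of 12 with 0 rises (camera adjusted p = 2.17e-05; adjusted p = 0.109 with an estimated correlation). Treg genes fell in 18 of 20 with 2 rises (camera adjusted p = 6.12e-05; adjusted p = 0.109 with an estimated correlation). Examples were Il12rb2 (-1.08 ± 0.028), Ccr5 (-2.49 ± 0.074), Ccr4 (-1.57 ± 0.034), Ccr8 (-1.12 ± 0.036) and Entpd1 (-1.11 ± 0.045), with Ctla4 higher at 43647 ± 1112. Cytokine receptor and JAK-STAT genes fell in 15 of 25 cases and rose in 5 (camera adjusted p = 0.00319; adjusted p = 0.195 with an estimated correlation). These include Il12rb1 (-1.26 ± 0.030), Il21r (-0.91 ± 0.028) and Tgfbr1, a receptor of the TGF-beta used in the culture (-0.66 ± 0.030).

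T cell identity genes fell in 15 of 15 cases (camera adjusted p = 1.00e-08; adjusted p = 0.109 with an estimated correlation), for example Cd2 (-1.05 ± 0.027), Cd5 (-0.86 ± 0.028), Lck (-0.76 ± 0.027) and the adaptor gene Lat (-0.77 ± 0.027). All 7 CD8 and NK cell markers fell (camera adjusted p = 0.0115; adjusted p = 0.195 with an estimated correlation), with Klrk1 at -1.24 ± 0.13 and Klrd1 at -0.86 ± 0.091. That call was lost without control replicate 2 (camera adjusted p = 0.0552) and with a CPM filter of 5 (0.143). These markers summed to 22.8 CPM with MS402, B cell markers to 70.1, myeloid markers to 4.04 and erythroid markers to 2.18, against 3754 CPM for T cell identity genes. Neither B cell markers (7 lower and 0 higher of 10, camera adjusted p = 0.0784), myeloid markers (1 lower and 0 higher of 8, camera adjusted p = 0.762) nor erythroid markers (1 higher and 0 lower of 3, camera adjusted p = 0.976) passed as lists.

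Myc and ribosome biogenesis genes fell in 27 of 30 cases and rose in 0 (camera adjusted p = 4.53e-15; adjusted p = 0.109 with an estimated correlation), for example Gnl3 (-1.53 ± 0.040), Nop2 (-1.12 ± 0.034) and Wdr43 (-1.04 ± 0.032). Of 24 cell cycle genes 18 fell and 4 rose (camera adjusted p = 0.00541; adjusted p = 0.130 with an estimated correlation). The cyclin genes Ccnd2 (-0.58 ± 0.024) and Ccnd3 (-0.42 ± 0.027) and Mki67 (-0.39 ± 0.025) fell, and the spindle checkpoint kinase gene Bub1 rose (0.55 ± 0.033). Histone genes rose in 13 of 19 cases and fell in 0 (camera adjusted p = 2.61e-05; adjusted p = 0.111 with an estimated correlation). H3f3b was at 1.27 ± 0.024, H1f0 at 1.41 ± 0.029 and Hist1h1c at 2.74 ± 0.082. Immediate early genes rose in 19 of 26 cases and fell in 4 (camera adjusted p = 2.71e-05; adjusted p = 0.1996 with an estimated correlation), with Egr1 at 1.48 ± 0.028 and Nr4a2 at 1.26 ± 0.060. BET and P-TEFb components (10 higher, 4 lower of 14; camera adjusted p = 0.0115; adjusted p = 0.1996 with an estimated correlation) included Mepce (0.79 ± 0.033). Glycolysis genes (13 higher, 1 lower of 18; camera adjusted p = 0.00436; adjusted p = 0.423 with an estimated correlation) included Pfkl (0.85 ± 0.026) and Pdk1 (0.39 ± 0.031).

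Not called as lists with MS402 were NF-kB target genes (14 lower, 8 higher of 25, camera adjusted p = 0.320) and stress response genes (9 higher, 8 lower of 20, 0.296). Nor were interferon response genes (7 lower, 3 higher of 17, 0.384) and cholesterol synthesis genes (7 lower, 5 higher of 18, 0.990). Hspa1b still rose (2.69 ± 0.081), the interferon-inducible GTPase gene Igtp fell (-0.70 ± 0.028), and the LDL receptor gene Ldlr fell (-0.54 ± 0.035). Naive and quiescence genes (11 lower, 7 higher of 18) and apoptosis regulators (13 lower, 2 higher of 18) lay at the threshold with the same camera adjusted p = 0.0563. The former passed without control replicate 2 (0.0483), JQ1 replicate 1 (0.0456) or JQ1 replicate 2 (0.0462). The latter passed without MS402 replicate 1 (0.0418) or MS402 replicate 2 (0.0381). Tcf7 (-1.02 ± 0.030) and Lef1 (-0.87 ± 0.032), transcription factors of naive T cells, fell, and Tob1 rose (1.49 ± 0.047). Bcl2l11 rose (to 3519 ± 0.980 from 1610 ± 29.7) and the caspase gene Casp8 fell (-0.86 ± 0.034).

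Limma called 9549 genes between MS402 and control, 4777 higher and 4772 lower. Of these, 2495 differed by at least 1.5-fold on the deposited log2 scale (1143 higher, 1352 lower) and 734 by at least 2-fold (332 higher, 402 lower). Camera called 14 of 23 lists (4 up, 10 down) and 0 with an estimated correlation (8 at an unadjusted p under 0.05), and fry called 20. Adjusted over the list alone, the counts were those over all genes except for stress response genes (10 in place of 9 higher) and myeloid markers (0 in place of 1 lower). The median of cholesterol synthesis genes was -0.015 with a mean of 0.021, and that of erythroid markers -0.067 with a mean of 0.044. Camera, which compares a list with all other genes, gave the direction up for both. Under total-count scaling the median of cholesterol synthesis genes was above 0.

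**Figure D2:**
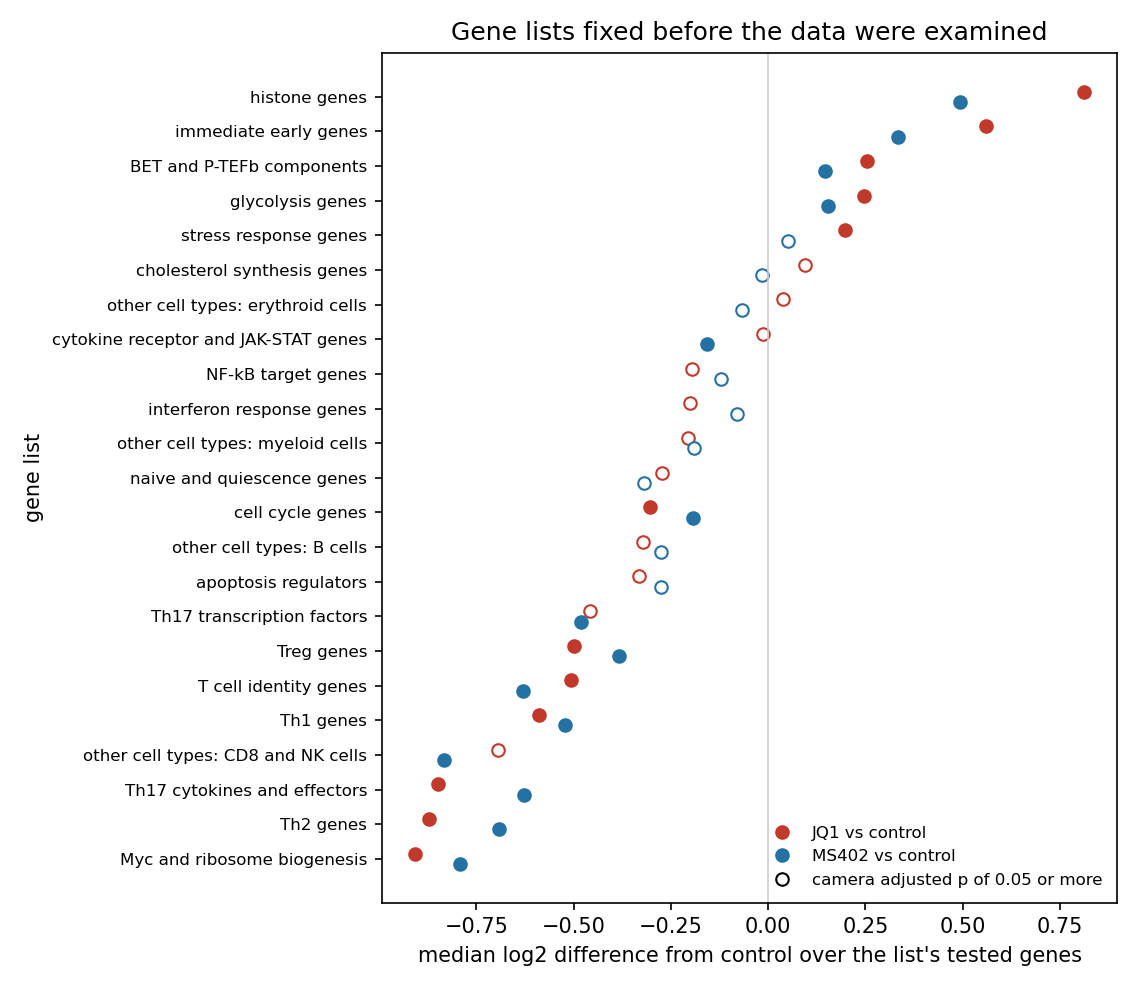
Median log2 difference from control (horizontal axis) of the tested genes of each of 23 gene lists, for JQ1 (red) and MS402 (blue), with open points where the camera adjusted p was 0.05 or more. Histone and immediate early genes lie highest, and Myc and ribosome biogenesis, Th2 genes and Th17 cytokines lie among the lowest.

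Where the compounds differed was tested directly, MS402 against JQ1. Their doses are not given in the sources used here, so the values are not at known matched doses. Myc was higher with MS402 than with JQ1, at 3248 ± 116 and 1840 ± 69.2 (SD, n = 2), and so was Il21, at 34994 ± 1101 and 25433 ± 101. Hexim1 was lower with MS402, at 4279 ± 148 and 6576 ± 49.2, and so was Brd2. Il17a and Il17f were slightly lower with MS402, at 3149 ± 98.5 and 3385 ± 8.73 for Il17a and 13720 ± 56.4 and 15117 ± 89.9 for Il17f. Immediate early, histone and stress response genes were mostly lower with MS402 than with JQ1, and cell cycle genes were more often higher than lower. Across all genes the MS402 response had a slope of 0.763 on that of JQ1, as given below. Under such a slope alone, lists that rose with JQ1 would tend to lie lower here, and lists that fell would tend to lie higher. Whether the lists depart from that slope was not tested.

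The log2 difference, MS402 minus JQ1, was 0.80 for Myc (95% interval 0.74 to 0.87), 0.46 for Il21 (0.41 to 0.51), -0.61 for Hexim1 (-0.69 to -0.54) and -0.30 for Brd2 (-0.35 to -0.25). It was -0.14 for Il17f (-0.19 to -0.088), -0.10 for Il17a (-0.17 to -0.034), 0.17 for Rorc (0.075 to 0.27) and 0.14 for Batf (0.044 to 0.24). For genes of other fates it was 0.20 for Foxp3 (0.075 to 0.33), 0.20 for Tbx21 (0.09 to 0.31) and -0.18 for Gata3 (-0.27 to -0.087), and it was -0.082 for Brd4 (-0.14 to -0.026). All 12 passed with limma, with adjusted p of at most 0.0118. The calls of the smaller differences did not all hold. That of Il17a was lost without JQ1 replicate 1 (limma adjusted p = 0.0519), JQ1 replicate 2 (0.0667) or MS402 replicate 1 (0.0981) and under total-count scaling (0.601). The calls of Rorc (0.228) and Tbx21 (0.175) were lost without MS402 replicate 1, and that of Gata3 was lost under total-count scaling (0.0597). Brd4 lost its call without JQ1 replicate 1 (0.116) or MS402 replicate 2 (0.0535) and under total-count scaling (0.965). Batf lost it without JQ1 replicate 2 (0.348) or MS402 replicate 2 (0.0879). Il17a, Rorc, Brd4, Tbx21 and Batf also lost their calls without the variance trend (0.0913, 0.112, 0.159, 0.0881 and 0.101).

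At a mean log2 CPM of at least 4, the 8 genes most above JQ1 with MS402 were the cytokine gene Il16 (1.18 ± 0.038), Cc2d1a (1.15 ± 0.050), Gpr83 (1.12 ± 0.045), Zfp518a (1.08 ± 0.052), Fut7 (1.08 ± 0.064), Ldoc1l (to 1305 ± 56.6 from 629 ± 17.1), Il7r (0.99 ± 0.040) and the splicing helicase gene Dhx38 (0.99 ± 0.040). Il16, for example, stood at 5965 ± 31.8 in control, 1113 ± 3.05 with JQ1 and 2595 ± 92.2 with MS402. Most below JQ1 under this limit, which leaves out Hspa1a, Hspa1b and Hist2h2be, were Bzrap1 (95% interval -1.08 to -0.92), Kctd12 (-0.98 ± 0.050), Hs3st3b1 (-0.88 ± 0.060), Tob1 (-0.84 ± 0.047), Serpine1, which encodes the plasminogen activator inhibitor PAI-1 (-0.78 ± 0.064), Fzd5 (-0.77 ± 0.060), the interferon-inducible GTPase gene Iigp1 (-0.76 ± 0.038) and Errfi1 (-0.75 ± 0.056). Serpine1 lay on both sides of control, at 697 ± 33.4 in control, 854 ± 11.7 with JQ1 and 477 ± 23.0 with MS402. The limma adjusted p of these 16 genes was at most 3.85e-19.

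Among the genes with the largest changes against control, the difference between the compounds had 95% intervals of -0.58 to -0.36 for Etv5, -0.55 to -0.38 for Sipa1l2, -0.72 to -0.47 for Kcnc3, -0.54 to -0.33 for Pdlim7, -0.34 to -0.10 for Trim62 and -0.57 to -0.38 for Neto2, which rose with both. For genes that fell with both, the intervals were 0.25 to 0.45 for Gja5, 0.84 to 1.03 for Gcnt2, 0.31 to 0.56 for Ubash3a, 0.76 to 0.97 for Slfn1, 0.79 to 0.93 for Ccr4, 0.65 to 0.90 for Phf19, 0.35 to 0.52 for Cysltr1, 0.16 to 0.32 for Pik3cg and 0.34 to 0.51 for Ncf1. Cyp1a1 differed little between the compounds, with means of 629.8 ± 7.24 for JQ1 and 628 ± 3.77 for MS402 and an interval of -0.11 to 0.10 (limma adjusted p = 0.958).

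**Figure D3:**
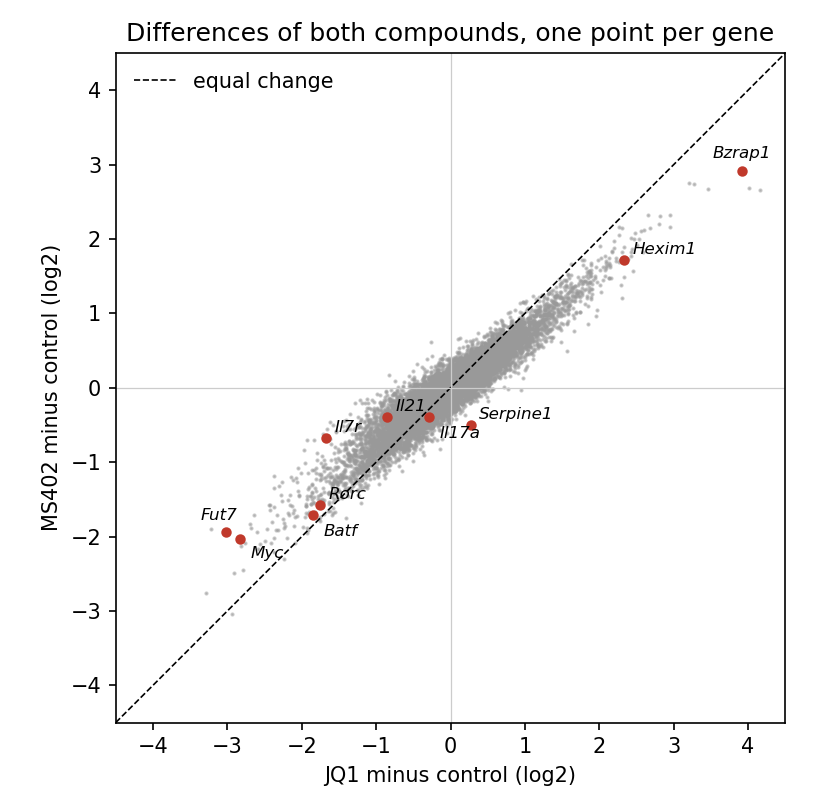
Log2 difference from control of each of 13447 genes with JQ1 (horizontal axis) and with MS402 (vertical axis), with 10 named genes in red and a dashed line of equal change. Genes such as Myc, Fut7, Bzrap1 and Hexim1 lie nearer to 0 with MS402, and Serpine1 lies on opposite sides of 0.

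Immediate early genes were lower with MS402 than with JQ1 in 19 of 26 cases and higher in 3 (camera adjusted p = 3.10e-07; adjusted p = 0.244 with an estimated correlation), for example Egr1 (-0.64 ± 0.028) and Ier5 (-0.53 ± 0.036). Histone genes were lower in 14 of 19 cases and higher in 0 (camera adjusted p = 2.36e-05; adjusted p = 0.244 with an estimated correlation), as H3f3b (-0.44 ± 0.024) and Hist2h2be (-1.07 ± 0.086). Stress response genes were lower in 13 of 20 cases and higher in 4 (camera adjusted p = 3.50e-04; adjusted p = 0.244 with an estimated correlation), as Hspa5 (-0.39 ± 0.024) and Hspa1b (-1.32 ± 0.081). BET and P-TEFb components were lower in 8 of 14 with 2 higher (camera adjusted p = 0.00369; adjusted p = 0.244 with an estimated correlation), as Aff4 (-0.33 ± 0.029). Naive and quiescence genes (10 lower, 3 higher of 18; camera adjusted p = 0.0126; adjusted p = 0.244 with an estimated correlation) held Btg1 (-0.63 ± 0.025) and Txnip (-0.72 ± 0.031). Glycolysis genes (12 lower, 2 higher of 18; camera adjusted p = 0.00946; adjusted p = 0.555 with an estimated correlation) and cholesterol synthesis genes (9 lower, 1 higher of 18; camera adjusted p = 0.0119; adjusted p = 0.244 with an estimated correlation) were called down too, with Slc2a1 (-0.25 ± 0.025) and Insig1 (-0.50 ± 0.033) as examples. Both calls were lost under total-count scaling (0.129 and 0.0706).

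Cell cycle genes were higher with MS402 in 12 of 24 cases and lower in 3 (camera adjusted p = 2.28e-04; adjusted p = 0.244 with an estimated correlation), as Mki67 (0.51 ± 0.025) and Plk1 (0.57 ± 0.036). Myc and ribosome biogenesis genes (16 higher, 7 lower of 30; camera adjusted p = 0.0438; adjusted p = 0.342 with an estimated correlation) and Th17 cytokines and effectors (7 higher, 5 lower of 19; camera adjusted p = 0.0446; adjusted p = 0.244 with an estimated correlation) were called up at the edge of the threshold. Within them Mybbp1a (0.24 ± 0.027) and Il10 (0.53 ± 0.027) were higher, and Odc1, the rate-limiting enzyme gene of polyamine synthesis (-0.36 ± 0.024), and Tnf (-0.49 ± 0.032) were lower. The Myc call was lost without JQ1 replicate 1 (0.0508) or MS402 replicate 2 (0.0519), and that of the cytokines without MS402 replicate 1 (0.0643) or MS402 replicate 2 (0.116).

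Lists not called between the compounds, by camera adjusted p, were Th17 transcription factors (7 lower, 4 higher of 18, 0.154), Th1 genes (5 higher, 2 lower of 16, 0.639), Th2 genes (4 higher, 4 lower of 12, 0.963) and Treg genes (7 higher, 5 lower of 20, 0.987). The same holds for cytokine receptor and JAK-STAT genes (11 lower, 5 higher of 25, 0.155), NF-kB target genes (10 higher, 6 lower of 25, 0.180), and interferon response genes (5 lower, 2 higher of 17, 0.362), and for apoptosis regulators (6 higher, 6 lower of 18, 0.987) and T cell identity genes (9 lower, 3 higher of 15, 0.155). Markers of B cells (1 higher, 0 lower of 10, 0.907), myeloid cells (0 higher, 0 lower of 8, 0.987), CD8 and NK cells (2 lower, 1 higher of 7, 0.963) and erythroid cells (1 lower, 0 higher of 3, 0.989) were not called either. Single members still differed, such as Stat3, the main signal transducer of IL-6 (-0.30 ± 0.025), Ccr4 (0.86 ± 0.034), Ctla4 (-0.49 ± 0.024), Mcl1 (-0.38 ± 0.027) and Itk (-0.37 ± 0.026). Medians and tests differed in sign for interferon response genes (median 0.03, camera down) and erythroid markers (median -0.038, camera up), and the medians of Th17 transcription factors and JAK-STAT genes, both below 0, were above 0 under total-count scaling.

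Between the compounds limma called 6677 genes, 3129 higher and 3548 lower with MS402. Of these, 340 differed by at least 1.5-fold on the deposited log2 scale (239 higher, 101 lower) and 19 by at least 2-fold (14 higher, 5 lower). That split depends on the scaling: with total counts 4589 were higher and 2229 lower, or 67.3% higher against 46.9%. Camera called 10 of 23 lists (3 up, 7 down) and 0 with an estimated correlation (2 at an unadjusted p under 0.05), and fry called 14. Adjusted over the list alone, the counts differed from those over all genes for Th17 transcription factors (8 in place of 7 lower), Th2 genes (5 in place of 4 higher), Myc and ribosome biogenesis (18 in place of 16 higher), BET and P-TEFb components (9 in place of 8 lower) and erythroid markers (0 in place of 1 lower).

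How far the 2 responses resembled each other was asked across genes. Genes that fell with JQ1, such as Myc, Rorc and Fut7, fell with MS402, and genes that rose, such as Hexim1 and Bzrap1, rose with it. In numbers, 4251 genes were called higher and 4216 lower with both compounds, and 163 in opposite directions (12 of them by over 0.2 log2 each). The 163 had passed each comparison singly. A stricter joint test took the larger of both p-values and adjusted it over all tested genes, with genes outside the pattern counted as unchanged. By that test 15 genes went in opposite directions, and 5 under each of 4 scalings. Serpine1 was not among the 5. Of the genes lower with both, 1917 were lower with JQ1 than with MS402, 390 were lower with MS402, and 1909 were not called between the compounds. The same kind of joint test was applied to the fall with JQ1 and the difference between the compounds. By it 207 genes fell further with MS402, but 85 under total-count scaling and 68, such as Lef1, Tgfbr1 and Ccnd3, under each of 4 scalings. Il17a and Il17f were not among the 68. Of the genes higher with both, 2190 were higher with JQ1, 131 higher with MS402 and 1930 not called. By the joint test 28 rose further with MS402, but 69 under total-count scaling and 8 under each of 4 scalings, so the balance of further falls and rises depends on the scaling. Pearson's r of the log2 differences across genes was 0.94, with a slope of 0.763 for MS402 on JQ1 (first principal axis), and 88.1% of genes had the same sign. Both comparisons use the same 2 control libraries, and unchanged groups simulated against them gave r = 0.502, 66.7% of genes with the same sign and 0 shared calls in 50 simulations. The covariance was 0.292 against 0.00354 in the simulation, a difference of 0.288. Independent lists of these sizes would share 1842 higher and 1857 lower genes. With 1 control library for each compound r was 0.916 and 0.919, and the covariance was 0.288 and 0.289.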

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

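Analyses with TMM scaling, voom on the recovered reads, log2(normalized count + 1) and no variance trend were chosen after seeing the data. Stricter thresholds were applied only to counts of genes. Under the other settings 25 of 349 results for named genes changed: of 5551 values 59 lost a call, 10 gained one and 0 reversed. Most named genes had been picked for a large change or a small p, so these counts say little about genes in general. Of the 12 genes named in every comparison, Il17a, Rorc, Brd4, Tbx21, Gata3 and Batf lost their call between the compounds in at least 1 setting. The counts of called genes stayed within 1.5 times of the main ones except where a fold change was also required. A fold change of at least 1.5 on the deposited scale left, by construction, 3858 genes for JQ1 against control, 2495 for MS402 against control and 340 between the compounds. Leaving out 1 library at a time gave 9704 to 10529, 8644 to 9448 and 5506 to 6527 calls. The group left with 1 library is then assumed to vary like the others. The correlation between the responses (0.94) was 0.927 without a filter, 0.947 with a CPM of at least 5, 0.931 with voom, 0.931 with log2(normalized count + 1) and 0.928 to 0.940 with 1 library left out. Shared calls (8467) ranged from 7208 to 8500.

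The replicate numbers do not pair the libraries: the correlations of same-numbered deviations were -0.0011, 0.034 and -0.013. With the replicate number as a block the counts were 10418, 9546 and 6669, r was 0.94, and 3 lists crossed the threshold: Th17 transcription factors (0.0149) and cytokine receptor and JAK-STAT genes (0.0424) with JQ1, and naive and quiescence genes with MS402 (0.0338).

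Some lists moved across the threshold of 0.05, and the cause was not tested. With JQ1, stress response genes (0.0447) lost their call under total counts (0.0629), no filter (0.0524), a CPM of at least 5 (0.0828), voom (0.0599) and log2(normalized count + 1) (0.0568), with 0.00205 to 0.0808 when 1 library was left out. CD8 and NK cell markers gained one without a filter (0.0108; 0.0430 to 0.202 with 1 library left out). Leaving out 1 library gave 0.0162 to 0.168 for Th17 transcription factors and 0.0420 to 0.299 for cytokine receptor and JAK-STAT genes. With MS402, without a filter, apoptosis regulators (0.0146) and B cell markers (0.0268) passed. The former also passed with log2(normalized count + 1) (0.0432; 0.0381 to 0.178 with 1 library left out) and naive and quiescence genes passed with voom (0.0477; 0.0456 to 0.0984). CD8 and NK cell markers were lost at a CPM of at least 5 (0.143; 0.0115 to 0.0552). Between the compounds, Th17 cytokines and effectors (0.0204 to 0.116 with 1 library left out) were lost under upper-quartile factors (0.0501), total counts (0.0523), no filter (0.0837), a CPM of at least 5 (0.0890), voom (0.0515) and log2(normalized count + 1) (0.0635). Myc and ribosome biogenesis (0.0342 to 0.0519) was lost under upper-quartile factors (0.0563), a CPM of at least 5 (0.0723) and voom (0.0702), and under total counts glycolysis (0.129) and cholesterol synthesis (0.0706) were. No scaling moved the median of all genes by more than 0.069 (log2). The intended tests of raw counts were not run, although the recovered reads would have allowed them. Voom was run on those reads. At a depth of at least 32624032 reads, genes near the filter of 10 normalized counts, such as the myeloid markers, remain poorly measured.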

Other observations

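The gene families here, and the tests of both patterns except the percentile among random lists matched on expression level, were chosen after the results were seen.

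Receptor genes for chemokines and microbial ligands fell together within 2 h of either compound. Of 16 tested chemokine receptor genes, 13 fell and 1 rose with JQ1 (median -1.06, camera adjusted p = 8.15e-04; adjusted p = 0.165 with an estimated correlation), and 14 fell and 1 rose with MS402 (median -1.11, camera adjusted p = 2.84e-04; adjusted p = 0.130 with an estimated correlation). Ccr6, the receptor that marks Th17 cells, went from 937 ± 8.68 normalized counts to 452 ± 20.4 and 411 ± 30.5 (SD, n = 2), Cxcr6 from 607 ± 3.80 to 185 ± 3.62 and 203 ± 1.07, and the 1 that rose with both was Ccr7, the lymph node homing receptor, at 22691 ± 158, 38679 ± 659 and 34361 ± 834. All 7 tested Toll-like receptor genes fell with both compounds (medians -1.29 and -1.22, camera adjusted p = 0.00483 and 0.00754; adjusted p = 0.187 and 0.180 with an estimated correlation), Tlr1 from 594 ± 13.0 to 82.4 ± 17.9 and 149.6 ± 2.98. Several were near the detection limit (Tlr4 at 47.2 ± 7.81 in control), and B cells and myeloid cells also express them. The cells had been purified as CD4+ T cells, and myeloid markers were not called as a list (camera adjusted p = 0.843 with JQ1 and 0.762 with MS402). Of 10 B cell markers 7 fell with each compound and all 7 CD8 and NK cell markers fell, so whether the fall lies in the Th17 cells was not determined. Genes with symbols of interleukin receptors fell in 20 and rose in 6 of 31 cases with JQ1, and in 24 and 6 with MS402 (camera adjusted p = 0.00564 and 7.22e-04; adjusted p = 0.165 and 0.130 with an estimated correlation). The symbols include Il1rn, which encodes a receptor antagonist and not a receptor (-1.09 ± 0.053 and -0.77 ± 0.053). Il23r, which sustains Th17 cells, fell (-0.82 ± 0.13 and -0.72 ± 0.13), while Il17ra, the receptor of IL-17 itself, rose (0.95 ± 0.031 and 0.47 ± 0.031).

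Further groups moved beside these. Of 5 aryl hydrocarbon receptor targets, Cyp1a1, Cyp1b1 (-2.40 ± 0.080 with JQ1 and -1.81 ± 0.080 with MS402) and Ahrr (-1.74 ± 0.058 and -1.43 ± 0.058) fell with both, and Tiparp rose with JQ1 (0.34 ± 0.031) and fell slightly with MS402 (-0.083 ± 0.031, limma adjusted p = 0.0142). As a list they gave a camera adjusted p = 0.0439 and 0.00413, and adjusted p = 0.217 and 0.130 with an estimated correlation. Schlafen genes, which are similar in sequence, fell in 6 and 5 of 7 cases, with Slfn4 the 1 that rose (camera adjusted p = 0.00483 and 0.00598; adjusted p = 0.165 and 0.130 with an estimated correlation). Cytosolic ribosomal protein genes rose slightly relative to other genes, 71 of 78 with JQ1 (median 0.18) and 41 with MS402 (median 0.057), while the ribosome biogenesis genes of the report fell. They gave a camera adjusted p = 3.57e-06 and 0.0238, and adjusted p = 0.391 and 0.599 with an estimated correlation. Between the compounds 68 were lower with MS402 and 1 was higher (median -0.11, camera adjusted p = 2.70e-09, and adjusted p = 0.286 with an estimated correlation). Under total-count scaling that median was -0.033, so its size depends on the scaling. The small rises against control can also mean that other RNA fell. Zinc finger genes named Zfp were higher with MS402 than with JQ1 in 148 of 306 cases and lower in 33 (median 0.15, camera adjusted p = 2.92e-06; adjusted p = 0.253 with an estimated correlation), with medians against control of -0.083 and 0.039 that were not called (camera adjusted p = 0.207 and 0.365). The medians named in these paragraphs kept their sign under TMM, upper-quartile and total-count scaling.

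Most genes that host small nucleolar RNAs (Snhg) were called higher with JQ1 and none with MS402: of 9 tested, 7 rose and 1 fell with JQ1 (median 0.23), 0 rose and 3 fell with MS402 (median -0.067), and 7 were lower with MS402 than with JQ1 (median -0.28). As a list they were called between the compounds (camera adjusted p = 0.00217; adjusted p = 0.253 with an estimated correlation), but neither with JQ1 (camera adjusted p = 0.217; adjusted p = 0.391 with an estimated correlation) nor with MS402 (camera adjusted p = 0.438; adjusted p = 0.599 with an estimated correlation). The tables argue against scaling, since the median difference stayed at -0.211 or lower under 3 other scalings, and against a trend with expression level, since 10000 random lists of other genes matched on level had a median of 0.0076 (the family's percentile, 0.04, is too low because it was chosen for its difference). The values over all genes argue against a JQ1 response scaled down by 1 factor. Of 13447 genes, 5272 departed from slope times JQ1 with MS402 (2881 below, 2391 above), and 5768 under total-count scaling. Of the 9 Snhg genes 8 lay under it, and 7 under total-count scaling. The family was chosen for this pattern, so its share adds no support. A lower dose with a response that differs from gene to gene stays open, as does a difference between cultures or harvests that goes with the compound.

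The MS402 response followed that of JQ1 with a slope under 1, with exceptions, and many genes were not called different between the compounds. The values argue against noise of the shared control libraries as the source of the resemblance, since the covariance was 82.5 times that simulated for unchanged groups. The simulation drew only on the spread within pairs of libraries. An offset of both control libraries, for example from vehicle or culture, would enter both comparisons and cannot be told apart. For the genes that moved less with MS402, a lower effective dose cannot be told apart from a property of the compound (slope 0.763), because doses are not given in the sources used here and go with the compound. A lower dose on a monotone response would not move genes further if total RNA stayed alike. With MS402, 76 genes moved the same way and further under each of 4 scalings (68 lower, 8 higher, among them Lef1, Tgfbr1, Ccnd3 and Igtp). All 4 scalings are relative, so a difference in total RNA between the compounds could also give such moves. The balance also went from 207 lower and 28 higher to 85 and 69 under total-count scaling, so these genes do not decide against a lower dose. Opposite moves would not follow from a lower dose on a monotone response either, if total RNA stayed alike. Under each of 4 scalings 5 genes moved so (Bin2, Ets1, Fkrp, Frmd4b and Tspan14). Ets1, for example, was at 0.32 ± 0.024 with JQ1 and -0.18 ± 0.024 with MS402. These 5 genes do not decide against a lower dose either, since the scalings are relative. A response that turns with dose, or a difference between cultures, could also give such exceptions and was not tested, so a distinct action of MS402 on those genes is a hypothesis, which a dose series of both compounds would test.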
